A study of Homo sapiens with 20 samples.

How the data were processed

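RNA of AZ521 cells with the inducible dnSox2 construct was hybridised to whole-transcript arrays. Per the labels' protocols, cells grew in minimum essential medium with 10% tetracycline-free serum, RNA was isolated with Trizol, and it was labelled with biotin through Affymetrix whole-transcript kits. The deposited log2 values are 1 normalized value per probe set and array, and per the submitters' processing notes RMA and Affymetrix Power Tools were used, with versions not given in the sources used here. RMA corrects background, makes the distributions of the arrays it is run on alike and summarises probes, so it compresses differences of dim genes. The values of the 8 h and 12 h arrays have 2 decimals and a mean array median of 6.33, and those of the 18 h and 24 h arrays have 5 decimals and a mean of 5.65. Correlations across probe sets were at least 0.992 within the first set, at least 0.987 within the second and between 0.947 and 0.969 across sets. Whether the sets were processed apart is not given in the sources used here. The median residual SD of genes was 0.0910 in the first set and 0.137 in the second. No scan dates, background levels or detection calls were used here, so signal over background is unknown and a dim gene's level may be background.

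The table has 33297 rows. The platform annotation listed 21214 of them, of which 19460 had 1 gene symbol and 1754 several, and 12083 were unlisted. Of the rows with 1 symbol, 19429 matched a gene identifier of the GRCh38.p14 gene table, and 0 symbols changed. The row with the highest mean over the 20 arrays stood for each gene, which gave 18417 genes and left out 1043 rows. Coordinates are not reported, since the files name no genome build. No 2 arrays held identical values. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

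Groups came from the labels: induced or uninduced at 8, 12, 18 or 24 h. All 20 arrays were fitted with limma 3.58.1 in R 4.3.3 with a mean per group, 12 residual degrees of freedom and 5.80 prior degrees of freedom, without a filter or a block. Same-numbered arrays of the 2 arms deviated together at 18 h, where the correlations of their deviations were 0.16, 0.21 and 0.36. These values are not independent, since deviations within a group cancel out and replicate 3 stood apart in both arms at 18 h. The numbers may thus pair the arrays at 18 h. At 8, 12 and 24 h no such correlation was over 0.1, and the labels give the numbers no meaning. Contrasts were induced minus uninduced at each time, their mean over the 4 times, the 24 h minus the 8 h difference, and uninduced 24 h minus 8 h. Moderated F tests were run over the 4 differences, over their changes with time and over the uninduced times. Benjamini-Hochberg adjustment ran over genes within a comparison, with a threshold of 0.05. Every gene was tested with a spread pooled over all arrays. The median residual SD over all arrays was 0.129, against 0.0910 in the 8 h and 12 h set and 0.137 in the later set. For a typical gene the pooled spread was thus too large at 8 h and 12 h and too small at 18 h and 24 h. Counts at the early times may therefore be too low, and those at the later times too high.

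For 36 gene lists written before the data were examined, limma's camera was run with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. The list of mitochondrially encoded transcripts had 0 measured genes and was not tested, leaving 35. Named genes followed a rule also set before the data were examined. It took genes past the threshold with every induced array on 1 side of every uninduced array of that time, and for the average at all 4 times. The 10 largest rises and 10 largest falls were taken at 18 h, at 24 h and for the average, and 5 and 5 at 8 h and 12 h. For the change between 24 h and 8 h, and for uninduced cells with no overlap of arrays, 5 and 5 were taken. SOX2 and up to 4 members of each list with the smallest p for the average difference were added. Not every gene that the rule took is named in the text. The genes named for the comparisons inside an array set, those that illustrate the arrays that stood apart and the lysosomal genes were chosen after their values were seen.

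The fit was tested on simulated data with the real means of 18417 genes and normal noise at each gene's pooled residual SD. The noise was drawn independently for each gene and array. It left out the unequal spread of the array sets, the arrays that stood apart from their groups and deviations shared between genes. The rates below therefore need not hold for the real arrays. At 8 h it recovered 50.7% of 67 genes changed 1.5-fold and 93.9% of 66 changed 2-fold, with 4 false calls. At 24 h it recovered 20.9% of 67 genes changed 1.25-fold, 65.7% at 1.5-fold and 98.5% at 2-fold, with 8 false calls. For the average it recovered 77.6% at 1.25-fold, with 14 false calls. In a second simulation of 18417 genes with the same independent noise, camera called a list of 28 genes raised 1.25-fold for the average difference, and 1 other list. How camera behaves with correlated genes was not simulated.

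The alternatives were centring each array on its median, cyclic loess, leaving out the 30% of genes with the lowest mean, testing every row, eBayes with trend and robust, fits of 1 time, replicate number as a block within time or across times, array weights, a 1.5-fold minimum, leaving out each array in turn and, for lists, an estimated correlation and fry. Added after seeing the data were fits without 3 arrays that stood apart from their groups, fits of 1 array set, time comparisons inside a set, and the 24 h against 18 h comparison without uninduced 18 h replicate 3. The 3 arrays were uninduced 18 h, induced 18 h and induced 24 h, each replicate 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.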

Results

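Gene expression was measured on 20 arrays of RNA from AZ521 cells, a human line that the labels describe as a gastric cancer line. Cell banks have reported stocks of this line as misidentified, and its tissue of origin was not tested here. The cells carried an inducible construct named dnSox2, a name in common use for a dominant-negative form of the transcription factor SOX2. Induced cells had received doxycycline at 1 µg/ml, and uninduced cells had not. No arrays of treated cells without the construct were analysed here, so for every gene the drug and the construct cannot be told apart. Samples were taken at 8 h and 12 h with 2 arrays per arm, and at 18 h and 24 h with 3 arrays per arm. The comparisons asked which genes differed between induced and uninduced cells at each time, whether the difference changed with time, and what changed with time without induction. The 8 arrays of 8 h and 12 h had median log2 values between 6.3 and 6.37, and the 12 arrays of 18 h and 24 h had medians between 5.61 and 5.68. The 8 h and 12 h values carried 2 decimals and the 18 h and 24 h values 5 decimals, so induced and uninduced levels were compared within a time, and any comparison of 8 h or 12 h with 18 h or 24 h also crossed these 2 sets of arrays. The number of arrays, 2 or 3 per arm, limited the precision of each difference.

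SOX2 signal was lower in induced than in uninduced cells, and at each time every induced array lay below every uninduced array. Uninduced means were 11.04, 11.12, 10.14 and 10.27 at 8, 12, 18 and 24 h, with SDs of 0.01, 0.04, 0.14 and 0.12. Induced means were 10.81, 10.65, 9.62 and 9.66, with SDs of 0.06, 0.05, 0.11 and 0.13. The log2 difference averaged over the 4 times was -0.46 with an SE of 0.05, a change of -27.2% (limma adjusted p = 1.64e-05). SOX2 passed the threshold at 18 h, at -0.52 (adjusted p = 0.00438), and at 24 h, at -0.61 (adjusted p = 0.000299). It did not pass at 12 h, at -0.47 (adjusted p = 0.178), or at 8 h, at -0.24 (adjusted p = 1). The difference between the 24 h and the 8 h effect, -0.38 with an SE of 0.14, did not pass either (adjusted p = 0.403). The labels do not say whether the SOX2 probes read the construct, the cells' own transcript or both, so the signal does not check the induction.

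**Figure D1:**
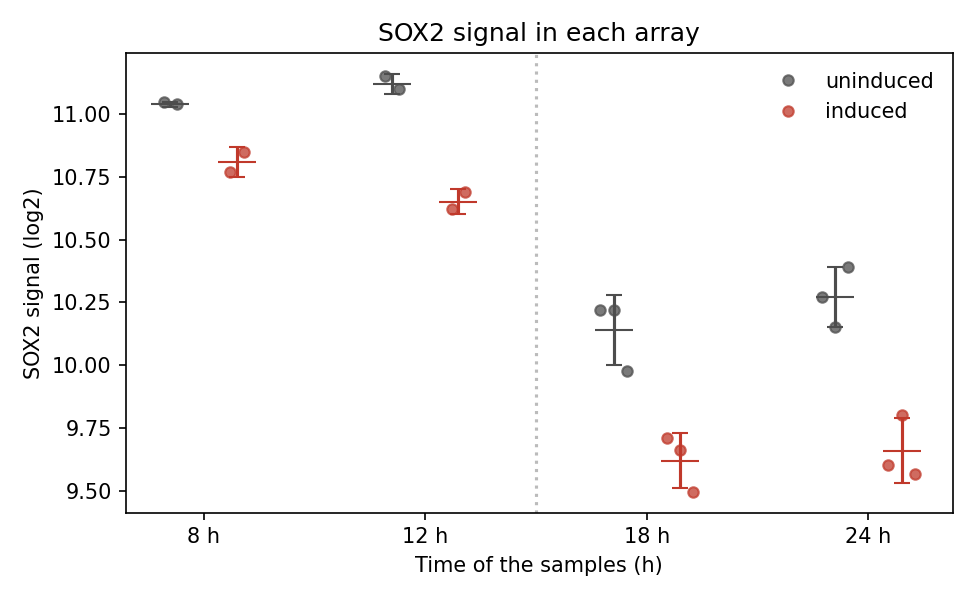
SOX2 signal (log2, vertical axis) in each of the 20 arrays by time (horizontal axis), with grey points for uninduced and red points for induced cells, the group mean as a horizontal line and the SD as whiskers. The dotted line parts the 2 array sets, and at 24 h the mean was 10.27 without and 9.66 with induction.

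At 24 h a broad set of genes differed between induced and uninduced cells. Among genes with 1 symbol, the named rises were led by CRABP2, IFITM1 and DKK4 and the named falls by XRCC4, MIR106A and PCDH18. A row without a single gene symbol had a larger fall, with a log2 difference of -2.304 in the fit of every row. CRABP2, the cellular retinoic acid binding protein, rose 4.31-fold from a mean log2 level of 5.58 ± 0.08 to 7.69 ± 0.21 (SD, n = 3 per arm). IFITM1, an interferon-induced membrane protein, rose 4.20-fold, and DKK4, a secreted Wnt antagonist, rose 4.02-fold. ELAVL3, a neuronal RNA-binding protein, rose 3.55-fold, and LEF1, a transcription factor of the Wnt pathway, rose 2.74-fold. IFI30, a lysosomal thiol reductase, rose 3.18-fold, and CD68, a lysosomal glycoprotein also used as a macrophage marker, rose 2.24-fold. LRCH2 rose 2.53-fold, GDF15, a stress-induced secreted factor of the TGF-beta family, 2.44-fold, and SFN, the 14-3-3 sigma protein, 2.20-fold. Among genes that fell, XRCC4, of DNA end joining, went from 6.31 ± 0.19 to 4.88 ± 0.11 (SD, n = 3 per arm), a log2 difference of -1.43. The probe sets of the microRNA genes MIR106A and MIR19B2, members of 1 cluster, fell by 1.37 and 1.18. The protocadherin PCDH18 fell by 1.31, the growth factor gene FGF10 by 1.27 and the matrix metalloproteinase MMP10 by 1.21. The lysophosphatidic acid receptor gene LPAR6 went from 6.64 ± 0.09 to 5.39 ± 0.17, a 2.38-fold fall. COQ3, of coenzyme Q synthesis, fell by 1.23, EGR1, an immediate-early transcription factor, by 1.16, and GOLPH3L, a Golgi protein, by 1.16. The SEs of these 20 differences lay between 0.07 and 0.21, and their limma adjusted p between 3.14e-10 and 0.000409. LRCH2 and MMP10 were among the 30% of genes with the lowest mean over all arrays, where a level may be background. In all, 1611 of 18417 genes passed, 750 higher and 861 lower, of which 16 rose and 23 fell at least 2-fold. Of those that passed, 742 higher and 855 lower genes had no overlap between the arms, which 10% of unchanged genes show by chance with 3 arrays per arm. Genes that pass limma are already chosen for a separation of the arms, so these counts add no evidence to the test. The count was 313 with a change of at least 1.5-fold, 1042 in a fit of the 24 h arrays alone and 958 in a fit of the 18 h and 24 h arrays. It was 1046, 1048 and 1046 without uninduced 24 h replicate 1, 2 or 3, and 1966 without uninduced 18 h replicate 3. Without the 3 arrays that stood apart from their groups, 1197 genes were higher and 1070 lower, so rises then outnumbered falls.

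Among the gene lists fixed before the data were examined, metallothioneins, Wnt targets and replication-dependent histones moved at 24 h. Metallothioneins are metal-binding proteins, and the list as written also held SLC30A1, which is not one of them. Of the 10 measured genes of this list, 7 rose and none fell, with a median log2 difference of 0.37 (camera adjusted p = 3.95e-05). MT2A rose by 0.71 (SE 0.09) and MT1G by 0.44 (SE 0.11). This list call did not hold with an estimated correlation (adjusted p = 0.385). Of 18 Wnt/beta-catenin targets, 5 rose and 1 fell, with a median of 0.07 (camera adjusted p = 0.00849; adjusted p = 0.385 with an estimated correlation). LEF1 rose by 1.45, ZNRF3 by 0.68, SP5 by 0.52 and AXIN2 by 0.51. ZNRF3 and AXIN2 encode negative regulators of the pathway. Of 24 histone genes, 9 fell and none rose, with a median of -0.20 (camera adjusted p = 3.24e-08; adjusted p = 0.406 with an estimated correlation). H4C2 fell by 0.64, H2AC8 by 0.57, H2BC8 by 0.53 and H2BC5 by 0.38. Adjusted over the list alone, 7 genes of the metallothionein list rose, 6 Wnt targets rose and 1 fell, and 11 histone genes fell.

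**Figure D2:**
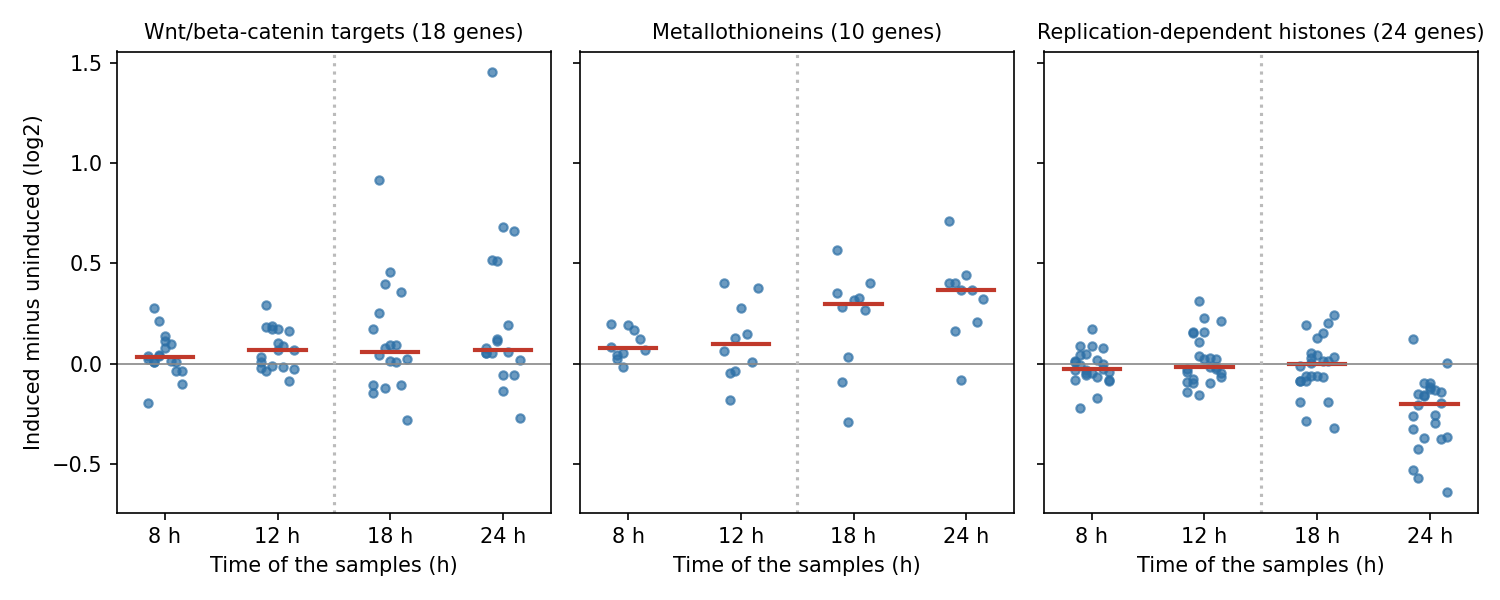
Induced minus uninduced log2 difference (vertical axis) of each measured member of 3 gene lists, 1 point per gene, at each time (horizontal axis), with the list's median as a red line and a dotted line between the 2 array sets. At 24 h the medians were 0.07 for Wnt targets, 0.37 for metallothioneins and -0.20 for histones.

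Other lists held genes that passed at 24 h without a shift of the whole list by camera. Of 20 p53 targets, 3 rose and 2 fell, among them CDKN1A, the cell cycle inhibitor p21, which rose by 0.75 (SE 0.09), and the death receptor FAS, which fell by 0.64. In the G1/S list 4 of 25 genes fell, among them TYMS by 0.48, GINS1 by 0.37 and MCM6 by 0.36. In the G2/M list 3 of 28 fell, namely CCNA2 by 0.44, CDC25C by 0.40 and PLK1 by 0.37. Of the MAPK feedback and immediate-early list, 2 of 21 rose and 3 fell: IER3 rose by 0.92, while DUSP6, a phosphatase of ERK, fell by 0.92 and SPRY2 by 0.45. Of 18 NF-kB and inflammatory genes, 3 rose and 5 fell, with LIF up by 0.40 and TNFAIP3, an inhibitor of the pathway, down (log2 difference -0.78), as were NFKB1 (-0.54) and RELB (-0.52). Of 14 Notch targets, 3 rose and 1 fell: NOTCH1 rose by 0.65 and NRARP by 0.55, and the ligand gene JAG1 fell by 0.56. Of 16 mesenchymal genes, 3 rose and 2 fell, and 11 lay above 0 and 5 below, with a median of 0.15. COL3A1, a fibrillar collagen, was at -1.07 and CDH2, N-cadherin, at -0.64. In the cholesterol synthesis list 5 of 16 genes fell, including MSMO1 by 0.76, CYP51A1 by 0.44 and SQLE by 0.35. The glucose transporter gene SLC2A1 rose by 0.84 and PFKFB4 by 0.67, while 4 of 21 genes of the hypoxia and glycolysis list fell, among them ADM by 0.44 and VEGFA by 0.35. The mucin gene MUC1 rose by 0.59, the only 1 of 17 gastric epithelium genes that passed, and none of 21 intestinal epithelium genes passed at 24 h (limma, median 0.04 in both lists), in a line whose tissue of origin is not settled here. Camera adjusted p for these lists lay between 0.0966 and 0.773, while fry called NF-kB and inflammatory genes (median -0.05, adjusted p = 0.0329) and Notch targets (median 0.15, adjusted p = 0.0461).

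At 18 h many of the same genes had moved, with GDF15 in front. GDF15 rose 2.60-fold from 7.68 ± 0.23 to 9.05 ± 0.26 (SD, n = 3 per arm), IFITM1 2.54-fold, DKK4 2.37-fold and CRABP2 2.35-fold. ELAVL3 rose 2.03-fold, SYT11, a synaptotagmin, 2.01-fold, CD68 1.91-fold, LEF1 1.88-fold, IFI30 1.86-fold and NEU1, the lysosomal sialidase, 1.86-fold. PCDH18 fell by 1.05 on the log2 scale from 11.57 ± 0.20 to 10.52 ± 0.40. PLEKHF2 fell by 0.97, FGF10 by 0.95 and LPAR6 by 0.93. EPHA7, an ephrin receptor, fell by 0.91, as did the ubiquitin ligase gene DTX3L, followed by ADAMTS18 and PCDHB2 at -0.88 and MMP10 at -0.86. Their SEs lay between 0.07 and 0.20, and their limma adjusted p between 9.92e-06 and 0.0110. In all, 483 genes passed, 262 higher and 221 lower, and 249 and 216 of them had no overlap between the arms. Metallothioneins shifted upward (median 0.30, camera adjusted p = 0.00205), with 2 of 10 past the threshold over all genes and 7 higher and 1 lower adjusted over the list alone. That shift gave an adjusted p of 0.753 with an estimated correlation, 0.0550 by camera without uninduced 18 h replicate 3, and 0.104 without 3 arrays that stood apart from their groups, replicate 3 of uninduced 18 h, induced 18 h and induced 24 h. Fry also called Wnt targets at 18 h (median 0.06, adjusted p = 0.0268), where camera did not (adjusted p = 0.0638). Of the genes called at 18 h, 218 higher and 172 lower genes were also called in the same direction at 24 h and 0 in the opposite direction, against 10.7 and 10.3 for independent lists. Both calls used 1 shared spread per gene, so the lists were not independent and these expected counts may be too low. The count at 18 h was 188, 212 and 1136 without uninduced 18 h replicate 1, 2 or 3, 278 and 229 without induced 18 h replicate 2 or 3, and 1010 without the 3 arrays that stood apart. It was 150 in a fit of the 18 h and 24 h arrays, 7 in a fit of the 18 h arrays alone and 99 with a change of at least 1.5-fold.

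Few genes passed at the early times, which were tested with a pooled spread larger than the typical spread of that array set. At 8 h, 1 gene passed, TMC1, a transmembrane channel gene, which fell by 0.98 from 6.02 ± 0.14 to 5.04 ± 0.12 (SD, n = 2 per arm; limma adjusted p = 0.0273). TMC1 was among the 30% of genes with the lowest mean over all arrays, so its level may be background. At 12 h, 3 genes rose and 13 fell. GDF15 rose 1.98-fold and the bitter taste receptor gene TAS2R4 1.90-fold, each at an adjusted p of 0.0476. POLB, DNA polymerase beta, fell by 0.91 (SE 0.12), the autophagy protease gene ATG4A by 0.86 (SE 0.10), DTX3L by 0.76 (SE 0.10), BCL9, a coactivator of beta-catenin, by 0.65 (SE 0.10) and MOCS3 by 0.64 (SE 0.11), at limma adjusted p between 0.00286 and 0.0288. The p53 target list shifted upward at 12 h, with a median of 0.09 (camera adjusted p = 0.0283; adjusted p = 0.686 with an estimated correlation), where 1 of its 20 genes, GDF15, passed over all genes and 3 rose adjusted over the list alone. Fry did not call it (adjusted p = 0.669). At an unadjusted p under 0.05 there were 502 genes at 8 h and 1367 at 12 h, against 921 expected by chance. TMC1 did not pass, and 0 genes passed at 8 h, without any 1 of the 4 arrays of 8 h, without uninduced 18 h replicate 1, uninduced 24 h replicate 3 or induced 24 h replicate 2, in fits of the 8 h arrays alone or of the 8 h and 12 h arrays, and without the 3 arrays that stood apart, and 2 genes passed without either induced 12 h array. The 12 h count was 0 without uninduced 12 h replicate 2 or induced 12 h replicate 1, 1 without induced 12 h replicate 2, and 8 without either 8 h array of either arm or without uninduced 24 h replicate 1, while it was 0 in a fit of the 12 h arrays alone, 1 in a fit of the 8 h and 12 h arrays, 73 without the 3 arrays that stood apart and 224 with array weights. TAS2R4 lost the threshold in 22 of 30 alternatives, and at 12 h GDF15 in 19 and MOCS3 in 14 of 31. TAS2R4 and ATG4A were also among the dimmest 30% of genes.

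Averaged over the 4 times, 1685 genes differed, 795 higher and 890 lower, and 182 and 234 of them had every induced array on the same side of every uninduced array at all 4 times. GDF15 was higher by 1.06 (SE 0.08), DKK4 by 1.01 (SE 0.07), CRABP2 by 1.00 (SE 0.06) and ELAVL3 by 0.94 (SE 0.06). LRCH2 (0.91), CD68 (0.69), SYT11 (0.65), IER3 (0.65), MICB, a ligand of an activating receptor of natural killer cells (0.62), and NEU1 (0.62) followed. MIR106A was lower at -0.80 (SE 0.10), DTX3L at -0.77 (SE 0.05), XRCC4 at -0.74 (SE 0.07) and PCDH18 at -0.74 (SE 0.08). LPAR6 (-0.72), PLEKHF2 (-0.71), GOLPH3L (-0.71), HILPDA, a lipid droplet protein gene (-0.70), and TMC1 (-0.65) followed, and limma adjusted p for these genes lay between 1.32e-08 and 0.000186. Most average changes were small, since 31 of the 1685 reached 1.5-fold. A joint test of the 4 differences called 1222 genes, 331 of them with a change of at least 1.5-fold at some time, and 2014 without the 3 arrays that stood apart. With array weights the average gave 2604 genes and the joint test 2009.

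On average over the times, the lists that shifted were metallothioneins (median 0.19, 5 of 10 higher, camera adjusted p = 6.34e-05), Wnt targets (median 0.05, 5 of 18 higher and 1 lower, camera adjusted p = 0.00306) and histones (median -0.07, 4 of 24 lower, camera adjusted p = 0.0413). With an estimated correlation none of the 3 held, with adjusted p = 0.224, adjusted p = 0.224 and adjusted p = 0.902, and the histone call was also lost without the 3 arrays that stood apart (adjusted p = 0.0700), with array weights, with either replicate block, with fry (0.240), without the dimmest 30% of genes and without any 1 of 10 single arrays. The metallothionein and Wnt lists were each called in 10 of 11 alternatives, all but the estimated correlation, with fry adjusted p = 0.000555 and 0.000223. These alternatives refit the same arrays, so they are not separate evidence. Adjusted over the list alone, 6 genes of the metallothionein list and 7 Wnt targets were higher, and 1 Wnt target and 6 histone genes were lower. YAP/TEAD targets, with a median of -0.07, lay at the threshold: camera gave an adjusted p of 0.0512, and 0.711 with an estimated correlation, while 4 of 11 alternatives, among them fry (adjusted p = 0.0173), and 6 of 20 fits without a single array called the list. Adjusted over the list alone 5 genes were lower, and over all genes CCN2 and AMOTL1, 2 of its 14 genes, at -0.24 and -0.19. Among 18 SOX family genes other than SOX2, SOX18 and SOX14 were higher, both by 0.36, and 0 were lower. Among pluripotency genes SALL4 was higher by 0.21 and SOX2 was the 1 of 13 that was lower. Of 14 TGF-beta and BMP targets, 4 were higher and 3 lower, with ID2 at 0.33, ID1 at 0.32, ID4 at -0.38 and TGIF1 at -0.33. Of 18 apoptosis regulators, XIAP (0.30) and BAD (0.16) were higher, and DIABLO (-0.31) and PMAIP1 (-0.29) lower. The heat shock gene HSPB1 was higher by 0.29, the tight junction gene CLDN1 was lower at -0.41 and the desmosome gene DSP was higher by 0.18. Of 25 ATF4 targets, 3 were higher, namely GDF15, DDIT3 (0.57) and FGF21 (0.23), and VLDLR was lower at -0.36. The same list lay above the group means in the 3 arrays that stood apart, by a median of 0.16, and so did HMOX1, by 0.47. In the NRF2 list HMOX1 (0.61) and OSGIN1 (0.44) were higher, and GCLM (-0.29) and GCLC (-0.21) lower. Among cell cycle inhibitors, CDKN1A (0.47), GADD45B (0.26) and 1 other were higher and CDKN2B (-0.25) and BTG3 (-0.19) lower. Of 21 interferon response genes only IFIH1, a sensor of viral RNA, passed on average, at -0.40. In lipid metabolism CPT1A (0.14) and FADS1 (0.13) were higher and the desaturase gene SCD lower (-0.18). Of 22 genes each, 1 rose and 1 fell in nuclear oxidative phosphorylation, NDUFB10 (0.23) and NDUFB5 (-0.32), and 1 rose and 3 fell in mitochondrial translation. Of 18 ribosome biogenesis genes 1 was higher and 2 lower, including WDR12 (-0.34), of 17 endoplasmic reticulum chaperone genes DNAJB11 was lower (-0.19), and of 17 neural genes PAX6 was lower (-0.15). No cytosolic ribosomal protein gene of 25 passed (limma, median -0.01). For the lists other than the 3 that shifted, camera adjusted p was at least 0.0512. Of the averages named here, FADS1 lost the threshold in 20, CPT1A in 19, BTG3 in 16, DSP in 14, PAX6 in 13 and DNAJB11 in 12 of 29 alternatives, and FGF21 in 15 of 28. HMOX1, BAD and XIAP each lost it in 6, SCD in 4, GCLC in 3 and AMOTL1 in 2 of 29.

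No marker list of another cell type passed camera, which tests a shift in 1 direction. On average, 1 of 12 blood and immune markers passed, CD68, which is also a lysosomal protein, and 0 of 12 endothelial markers passed by limma (medians -0.02 and -0.01). Of 12 fibroblast markers, THY1 (0.23) and COL1A1 (0.15) were higher and COL3A1 (-0.51) and LUM (-0.25) lower, with a median of -0.07. Camera adjusted p of these 3 lists lay between 0.637 and 1.00. For changes in either direction, fry gave an adjusted p of 1.46e-10 for fibroblast, 5.84e-10 for blood and immune and 0.159 for endothelial markers. This test called 33 of the 35 lists, so it does not set these markers apart from other lists.

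The effect of induction differed between 24 h and 8 h for 66 genes, 30 with a more positive and 36 with a more negative difference at 24 h. The log2 difference of IFITM1 went from -0.15 at 8 h to 2.07 at 24 h, that of CRABP2 from 0.27 to 2.11 and that of IFI30 from 0.06 to 1.67. DKK4 went from 0.47 to 2.01 and ELAVL3 from 0.33 to 1.83. EGR1 went from 0.10 to -1.16, COQ3 from -0.08 to -1.23, XRCC4 from -0.30 to -1.43, MMP10 from -0.20 to -1.21, and the long non-coding RNA gene MIR31HG from 0.15 to -0.92. By limma's interaction these 10 genes had adjusted p between 1.24e-06 and 0.0243. The genes that went up kept the threshold in every alternative. Of those that went down, COQ3 lost it in 8, MIR31HG in 4, EGR1 in 3 and XRCC4 in 2 of 29 alternatives, and MMP10 in 3 of 28. Between these times Wnt targets (median 0.06) and metallothioneins (0.25) shifted upward, and MAPK feedback genes (-0.14), ATF4 targets (-0.22) and histones (-0.23) downward, at camera adjusted p between 2.99e-06 and 0.0436. With an estimated correlation none passed (adjusted p = 0.694 at the lowest), and without the 3 arrays that stood apart Wnt targets and metallothioneins each had a camera adjusted p of 0.103. Fry called none of these 5 lists (adjusted p = 0.0772 at the lowest). Over any pair of times, 45 genes differed. Inside 1 array set, 0 genes differed between 12 h and 8 h by limma, with 625 at an unadjusted p under 0.05, and 1 differed between 24 h and 18 h, IFI30, with a gain of 0.77 (SE 0.11, adjusted p = 0.0165). The count of 66 was 437 with array weights and 271 without the 3 arrays that stood apart. Leaving out 1 array in turn gave between 9, without induced 8 h replicate 2, and 116, without uninduced 18 h replicate 3, and the other arrays that moved it over 1.5 times are given with the processing alternatives.

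**Figure D3:**
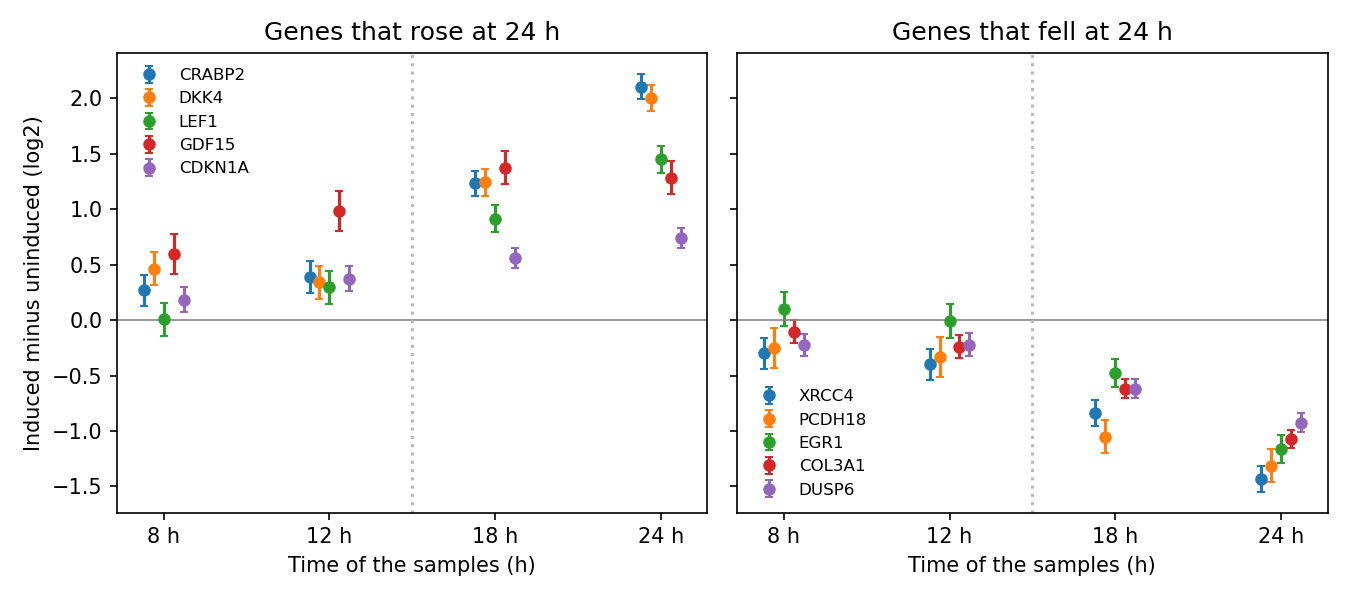
Induced minus uninduced log2 difference (vertical axis) of 5 genes that rose and 5 that fell at 24 h, at each time (horizontal axis), with the SE of the fit as whiskers and a dotted line between the 2 array sets. CRABP2 went from 0.27 at 8 h to 2.11 at 24 h, and XRCC4 from -0.30 to -1.43.

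Without induction, 14998 of 18417 genes differed between 24 h and 8 h, 625 higher and 14373 lower, and the median over all genes was -0.57. The 2 times lay in different array sets, so time and array set cannot be told apart in this comparison. The small nuclear RNA genes RNU5E-1 (2.33) and RNU5D-1 (1.95), the small nucleolar RNA gene SNORA22 (2.01), FLRT2 (2.02) and the histone gene H2AC14 (1.85) were higher in the 24 h arrays. The taste receptor genes TAS2R19 (-3.46), TAS2R31 (-3.38) and TAS2R43 (-3.33), ANKRD36 (-3.28) and NRIP1 (-3.12) were lower, and limma adjusted p for these 10 genes was at most 8.70e-08. After each array was centred on its median, 5998 genes were higher and 4151 lower with a median of 0.09, and after cyclic loess 5163 were higher and 4742 lower with a median of 0.04. Over any time, 15896 genes differed. Inside a set, 0 genes differed between 12 h and 8 h by limma, with 1684 at an unadjusted p under 0.05, and 2 between 24 h and 18 h, the small nucleolar RNA genes SNORD82 (0.87, SE 0.12) and SNORD63 (0.62, SE 0.09). Without uninduced 18 h replicate 3, which stood apart, 373 genes differed between 24 h and 18 h. By camera 5 lists shifted between 12 h and 8 h: G1/S genes upward (median 0.17, adjusted p = 0.000470), and p53 targets (-0.13), heat shock genes (-0.13), ribosomal proteins (-0.08) and histones (-0.05) downward, each at an adjusted p of 0.00433. With an estimated correlation none of the 5 passed (adjusted p = 0.264 at the lowest). Between 24 h and 18 h ATF4 targets had a median of 0.32 (camera adjusted p = 2.87e-11; adjusted p = 0.383 with an estimated correlation) with 0 of 25 genes past the threshold by limma. In the 3 arrays that stood apart, of which uninduced 18 h replicate 3 belongs to this comparison, the list lay above the group means, and without that array the median was 0.43 (camera adjusted p = 4.59e-16; adjusted p = 0.459 with an estimated correlation). Cholesterol synthesis genes had a median of 0.19 (camera adjusted p = 1.01e-05; adjusted p = 0.163 with an estimated correlation). Histones (median 0.09), ribosomal proteins (0.08), G1/S genes (0.10) and oxidative phosphorylation genes (0.06) also shifted upward, and intestinal epithelium genes (-0.14), SOX family genes (-0.10) and p53 targets (-0.14) downward, at camera adjusted p between 0.000466 and 0.0311. With an estimated correlation none of these 7 passed (adjusted p = 0.383 at the lowest). Without uninduced 18 h replicate 3 the SOX family call was lost (camera adjusted p = 0.0642), the histone median was 0.17 and the other 6 kept their calls.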

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

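The test of the integrated stress response below was chosen only after its result was seen, and so was the error over arrays used for the slope of the 24 h on the 18 h differences. The induction effect differed between 24 h and 8 h for 66 genes and between any times for 45 genes, by limma's interaction tests. The 24 h minus 8 h differences were 2.22 for IFITM1, 1.84 for CRABP2, 1.61 for IFI30, 1.54 for DKK4 and 1.502 for ELAVL3. They were -1.26 for EGR1, -1.16 for COQ3, -1.13 for XRCC4, -1.06 for MIR31HG and -1.01 for MMP10. The named genes leave out 13837 rows without a single gene symbol, which were unlisted or had several symbols. Of these rows, 245 passed at 24 h, 84 higher and 161 lower, in the fit of every row. Among those that passed, the largest rise was 1.985 and the largest fall -2.304. That fall was larger than any of the named genes at 24 h.

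Larger effects at 24 h than at 8 h were weighed against 2 technical explanations. Fewer arrays alone did not account for the larger count of genes at 24 h. With 2 arrays per arm, 24 h still called at least 699 genes over 9 subsets, against 16 at 12 h. That test compared counts, used 12 h in place of 8 h and did not test the size of effects. The pooled spread, too large for a typical gene at 12 h and too small at 24 h, may widen the gap. The 12 h count ranged from 0 in a fit of the 12 h arrays alone to 224 with array weights. Compressed fold changes in the 8 h and 12 h arrays stay open: the slope of the 24 h on the 18 h difference over the 483 genes called at 18 h was 1.08. Its SE was 0.026 by the bootstrap over genes, the error planned for the test, by which the slope exceeded 1. That was the result set beforehand as against compression. Yet the slope uses only 18 h and 24 h arrays, so it cannot show whether the early arrays were compressed. Choosing the genes at 18 h also biases it below 1. The bootstrap error also leaves out the spread between arrays. The jackknife SE over arrays, 0.18, put in its place after the result was seen, does not separate growth from none inside the later set. The SD of gene levels in the early set was 0.995 of that in the later set, so no overall narrowing was seen, and growth of the effect with time stays open beside the array set.

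Lower SOX2 signal in induced arrays was not removed by scaling between arrays, since after cyclic loess the average difference was -0.44 with an SE of 0.05. An effect of doxycycline without the construct stays open, because 0 arrays of treated cells without the construct were analysed here. Whether the probes read the construct was not tested.

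Uninduced 18 h, induced 18 h and induced 24 h replicate 3 stood apart from their groups, with scores of 20.6, 13.3 and 18.3 on a component that held 36.6% of the deviations in the 18 h and 24 h arrays, against -13.0 to 2.6 for the other 9. Their mean deviation was lowest for SEPTIN7P13 (-0.69) and ANKRD20A8P (-0.58) and was 0.47 for HMOX1. Across genes, which are not independent, the deviation had a Spearman correlation of -0.248 with gene length, between the bounds set for and against a length effect. The median deviation of 25 ATF4 targets, 0.16, lay at percentile 100 of 10000 random lists matched on mean level, whose central 95% ran from -0.06 to 0.07. Random lists ignore the correlation between members and the list was chosen once it was seen to be high, so a stress response stays open, and a difference in RNA handling was not tested.

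At 18 h, 1 of 10 splits of the 6 arrays gave as many genes as the real 483, with 360 as the highest other, which parted 1 of the 3 same-numbered pairs; the other splits that parted all 3, as the real one does, gave at most 1. At 24 h 1 of 10 gave as many as 1611, with 0 as the highest other. At either time 10 splits are too few for a share under 0.05. For the average, 1 of 100 splits drawn within times gave as many genes as the real 1685, namely the real one itself. The highest other split gave 1. For the joint test 1 of 100 gave as many as 1222, again the real one, with 755 as the highest other. In both tests the share was under 0.05, so a random division of these arrays seldom gave such counts. The draws did not keep same-numbered arrays in separate arms. They cannot tell induction from another difference between the arms.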

How the results depend on the processing

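The fits without the 3 arrays that stood apart, of 1 array set and inside a set were chosen after seeing the data. All 183 named gene results kept their direction in every alternative that was run, and 129 of them also kept the threshold in each. These genes were chosen for passing the threshold, and many also for arms without overlap. Their kept direction in refits of the same arrays therefore adds no evidence. The average SOX2 difference kept its side throughout. Of 483 genes called at 18 h, 406 were shared with the fit without the 3 arrays, as were 1405 of 1611 at 24 h and 1588 of 1685 on average. Unless a sentence gives it, the cause was not tested. How far signal stood over background is unknown, which limits dim genes.

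Cyclic loess gave 9905 genes for uninduced 24 h against 8 h. Without the dimmest 30% of genes, the 8 h count was 0 and the 24 h against 8 h effect 109. With every row, where more rows were tested, the counts were 0 at 8 h, 27 for the 24 h against 8 h effect, 16 for an effect differing between any times, 25725 for uninduced 24 h against 8 h and 27597 for uninduced cells over any time. Trend and robust gave 71 for any difference of effects. Fits of 1 time, with fewer arrays and their own spread, called 0 at 8 h, 0 at 12 h, 7 at 18 h and 1042 at 24 h. Array weights gave 2 at 8 h, 224 at 12 h, 2604 on average, 2009 at any time, 437 for the 24 h against 8 h effect and 172 for any difference of effects. A minimum of 1.5-fold left 9 at 12 h, 99 at 18 h, 313 at 24 h, 31 on average, 331 at any time and 9222 for uninduced 24 h against 8 h. With an estimated correlation 0 lists passed on average, against 3.

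Without the 3 arrays that stood apart, counts were 0 at 8 h, 73 at 12 h, 1010 at 18 h, 2014 at any time, 271 for the 24 h against 8 h effect and 181 for any difference of effects. Fits of 1 array set, each with its own spread, gave 0 at 8 h, 1 at 12 h, 150 at 18 h and 958 at 24 h. Inside a set, the effect differed for 0 genes between 12 h and 8 h and 1 between 24 h and 18 h, and uninduced cells for 0 and 2.

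Same-numbered arrays deviated together at 18 h, where all 3 pairs had a correlation over 0.1, and not at the other times, with 0 of their 7 pairs. The pairs of a time are not separate evidence, since deviations within a group cancel out. At 18 h replicate 3 stood apart in both arms, which by itself moves the other pairs together. With a replicate block within time the 18 h count was 465, and no named gene or list of 18 h lost its call; the other counts it moved were 0 at 8 h, 1 at 12 h, 43 for the 24 h against 8 h effect and 13 for any difference of effects. With a replicate block across times they were 736 at 18 h, 110 and 74. The block within time cannot give the uninduced time comparisons.

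Leaving out each array in turn, which leaves a lone array assumed to vary like the rest at 8 h and 12 h, gave 0 to 2 genes at 8 h, 0 to 18 at 12 h, 188 to 1136 at 18 h, 1046 to 1966 at 24 h, 1153 to 2088 on average, 860 to 1720 at any time, 13546 to 15168 for uninduced 24 h against 8 h and 15208 to 16188 over any uninduced time. The 24 h against 8 h effect gave 9 to 116 and any difference of effects 7 to 94. The former was 10 and 14 without uninduced 8 h replicate 1 or 2, 13 and 9 without induced 8 h replicate 1 or 2, 25 and 33 without uninduced 24 h replicate 1 or 3, 41 without induced 24 h replicate 1 and 116 without uninduced 18 h replicate 3. Any difference of effects was 7 to 23 without any 1 array of 8 h or 12 h, or of 24 h except induced replicate 2, and 94 without uninduced 18 h replicate 3.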

Other observations

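Lysosomal genes other than CD68, NEU1 and IFI30 were examined because these 3 were among the largest rises, as a list written after those values were seen and before its own test. At 24 h, 26 of 34 lysosomal genes lay above 0, 8 passed upward and 1 downward, and the median log2 difference was 0.16. The protease genes CTSB (0.69, SE 0.10, adjusted p = 0.000330) and CTSD (0.33) rose, as did CTSA (0.50), the lysosomal calcium channel gene MCOLN1 (0.47) and the proton pump genes ATP6V0A1 (0.45) and ATP6V0D1 (0.38), while ARSB fell by 0.23 (limma). At 18 h 27 of the 34 lay above 0 and 4 passed, with a median of 0.15 (camera p = 2.97e-06; p = 0.0828 with an estimated correlation), and at 8 h and 12 h none passed by limma, with medians of 0.05 and 0.01. Camera gave p = 0.000183 with the preset correlation and p = 0.156 with an estimated correlation at 24 h, so a rise of the lysosome as a group may be proposed as a hypothesis but was not settled by this test.

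PCDHB2 was among the largest falls at 18 h, and a fall of the neighbouring protocadherin beta genes with it was tested at 24 h as a hypothesis. Of the 15 other members, 10 lay above 0 and 5 below at 24 h, none passed by limma, and camera gave p = 0.585 with an estimated correlation, against a fall of the cluster at that time. At the other times more members lay below 0: 9 of 15 at 8 h (camera p = 0.0434; p = 0.124 with an estimated correlation), 9 at 12 h (p = 0.694 and p = 0.753) and 10 at 18 h (p = 0.160 and p = 0.272). A fall of the cluster before 24 h was not settled by these values.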
